A study of Mus musculus with 2 samples.

How the data were processed

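ATAC-seq of 2 libraries of mouse common myeloid progenitors was used, as 13 deposited peak lists on the mm10 assembly. Per the labels, the libraries were biological replicates 1 and 2 of 1 group. The labels of replicate 1 name 2 sequencing instruments and those of replicate 2 none. The aligner and peak caller are not given in the sources used here, nor is any shift of reads for the transposase offset. Per the deposited notes beside the files, lists of a replicate were derived from its filtered alignments and lists of the series from those of both replicates. A list of replicated peaks is archived there and was derived from earlier files.

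Each deposited peak has a signal value whose scale is not stated. It was used to rank, describe and filter regions within a list and to correlate shared regions between the replicates. For chromosome X, −log10 p was also related to it. The deposited lists also give −log10 p and q values, and the ranked lists −log10 values of the irreproducible discovery rate (IDR). The score of the deposited ranked lists was used to find which ranked peaks passed the IDR threshold: the conservative list held the peaks with a score of at least 540, apart from 101 on unplaced scaffolds and 161 on chromosomes. The lists hold no read counts, so depth per library is unknown and no count test was possible. The precision of a share is its binomial interval over regions, which covers counting error only.

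Overlapping peaks of a list were merged into regions that kept the summit and signal of the strongest peak, on chromosomes 1 to 19, X and Y. The conservative IDR-thresholded list of both replicates was the main set, as labelled. It held more peaks (102186) than the series IDR-thresholded list (99419), for which the labels give no reason, and the latter was run as an alternative. Each replicate's own IDR-thresholded list served to compare the replicates. Regions were set against GENCODE M21 and the GRCm38.p6 sequence, which is the build of the files. A region was a promoter region when its summit lay within 1 kb of a start of a protein-coding transcript, and distal otherwise. A gene had a promoter region when any region came within 1 kb of any of its starts, of which the 21853 genes have 54361. Distal regions were given to the nearest start within 100 kb.

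Regions of the replicates were shared when they met by at least 1 bp, with exact binomial intervals, beside 100 circular shifts of the other list. Wilson intervals were used for the promoter share, and intervals of odds come from the standard error of their logarithm. Fisher's exact test compared promoter with distal regions, list genes with other genes, and summit with flank windows. The motif windows reached 50 bp each side of the summit, the flanks were centred 500 bp away outside any region, and a match was to the whole consensus on either strand. Distal regions per gene were tested by permutation against 10000 random lists matched on the decile of territory length, and replicates by the exact McNemar test. Benjamini-Hochberg adjustment was over the 14 lists or the 33 motifs. Of 177 list symbols 176 matched, and the symbol without a match and some other members are not reported here by name. Listed enhancers were sought within 2 kb of their offset, against 1000 draws of random genes.

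Lists, motifs, enhancers, tests and most alternatives were fixed before the data were examined. The alternatives were other peak lists, the upper 50% of regions, either replicate alone, promoter windows of 500 and 2500 bp, other overlap rules, assignment within 50 kb, no territory matching, motif windows of 100 bp, GC-matched windows, enhancer tolerances of 1 and 5 kb and other gene backgrounds. GC matching drew equal numbers of summit and flank windows within classes of GC content. Summits without enough flanks of like GC content were therefore left out. The archived list, a background without olfactory, vomeronasal and taste receptor genes, and the enhancer control around the same genes were chosen after seeing the data. Any list member or listed enhancer could be named, and beyond these the 10 genes with the most distal regions, the 10 with the strongest promoter region, the 10 strongest distal regions, and at most 10 motifs with the highest odds. GATA and C/EBP are named outside this rule, after their values were seen, because they changed direction at promoters with GC matching.

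The methods were tested on simulated data. For lists of 12 genes, the distal test called 6% of 100 lists with no change, 50% with counts 2 times as high and 91% with counts 3 times as high, at an unadjusted 0.05. The promoter test called 6% with no change and 100% with all promoters open. In the latter setting each list had 12 of 12 open, so the result was the same each time by construction. Of 20000 random windows, 988 were given a PU.1 site, 1045 were found with a match, and 1 other motif passed the adjusted threshold. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used, and BLAST+ 2.17.0 for the sequence searches. Matches to the mitochondrial genome needed 50 bp at 80% identity, and near-identical copies 95% identity over 80% of the region, with a word size of 48.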

Results

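Open chromatin was measured by ATAC-seq, in which a transposase cuts and tags accessible DNA, in common myeloid progenitors of mouse. These are bone marrow progenitors from which erythroid, megakaryocytic, granulocytic and monocytic cells arise. The cells came from C57BL/6J males aged 5 to 6 weeks, with 50000 cells per library. The 2 libraries form 1 group and are labelled biological replicates 1 and 2. Both carry the same donor label, and nothing in the labels says that they came from separate animals, so differences between them may be technical. There was no second cell type or treatment, so the comparisons are between the replicates and between classes of regions and genes within the group. The deposited values are peak lists without read counts, so the sequencing depth of each library is unknown. Intervals cover counting error over regions only, and regions and genes are not independent replicates.

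Accessible regions of the group numbered 67395 after overlapping peaks of the conservative list of both replicates were merged, and they covered 38.04 Mb, 1.40% of the genome. Their median width was 498 bp. Replicate 1's own list held 47535 regions and that of replicate 2 held 37620. Of the replicate 1 regions, 72.3% met a region of replicate 2 by at least 1 bp (exact 95% binomial interval 71.9 to 72.7), and of the replicate 2 regions 91.8% met a region of replicate 1 (91.5 to 92.1). After circular shifts of the other list along each chromosome the same shares averaged 1.66% and 2.11%. Strong regions recurred most often. In replicate 1, 43.3% of the weakest 4754 regions and 98.7% of the strongest 4754 by signal were found in replicate 2. In replicate 2 the shares were 78.6% of the weakest 3762 and 99.8% of the strongest 3762. With the same number of strongest regions from each replicate the shares were 78.8% and 79.5%.

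**Figure D1:**
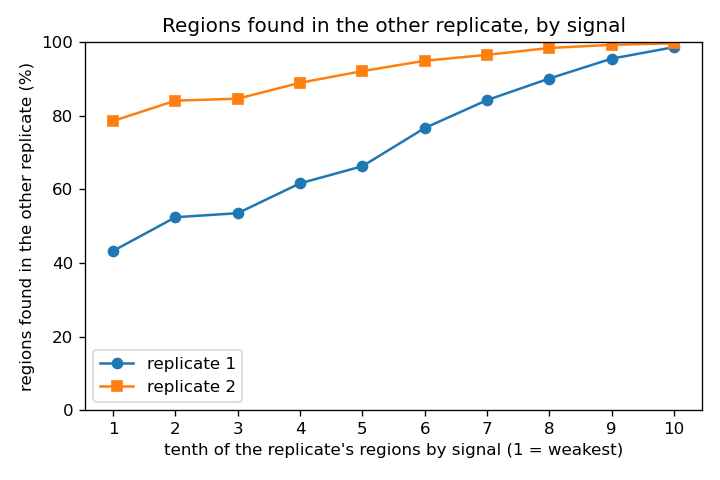
The percentage of each replicate's regions found in the other replicate (vertical axis) against 10 equal classes of the regions by peak signal, weakest first (horizontal axis). Circles are replicate 1 and squares replicate 2, and both lines end above 98% in the strongest class, starting from 43.3% and 78.6%.

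Peak strengths of shared regions ranked alike in both replicates. Across 34356 shared regions, Spearman's rho of the log2 peak signal was 0.879 and Pearson's r was 0.883. Promoter regions ranked more alike, with rho 0.919 over 10880 regions, than distal regions, with rho 0.855 over 23476. These correlations run across regions, which are not independent replicates, so no p-value is given.

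Promoters of protein-coding genes held 14789 of the 67395 regions, 21.9% (Wilson 95% interval 21.6 to 22.3), against 2.51% of circularly shifted regions, an 8.73-fold excess. Introns held 36.8% against 35.7% of shifted regions, and exons 3.00% (2.87 to 3.13) against 2.41%, a 1.24-fold excess. Intergenic regions made up 38.3% against 59.3% of shifted regions, 0.646 times that share. Promoter regions were wider, with a median of 770 bp against 454 bp in introns and 456 bp between genes, and had a higher median signal, 9.33 against 7.96 and 8.39. The promoter share differed between lists: it was 26.8% in replicate 1's own list, 30.2% in that of replicate 2 and 13.3% in an archived list of 222910 regions.

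Promoter regions recurred between the replicates more often than distal regions. In replicate 1, 85.4% of 12741 promoter regions and 67.5% of 34794 distal regions were found in replicate 2, an odds ratio of 2.82 (95% interval 2.67 to 2.98). In replicate 2, 97.1% of 11354 promoter regions and 89.5% of 26266 distal regions were found in replicate 1, an odds ratio of 3.89 (3.47 to 4.37, Fisher's exact test, two-sided, p = 8.83e-158). With at least 50% reciprocal overlap the odds ratios were 2.36 and 1.70, and with a promoter window of 500 bp 3.36 and 5.36. The order was the same in each of 3 equal classes of signal: in the weakest class of replicate 1 the shares were 62.1% and 46.6%, and in the strongest 99.0% and 91.5%.

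Promoters of progenitor and early erythroid genes were open, and those of mature neutrophil genes and of genes of other tissues were mostly without a region in the conservative list. Over all 21853 protein-coding genes, 13293 (60.8%) had a region within 1 kb of a transcription start. Of 18 stem and progenitor regulators, 17 had one, including Kit, the stem cell factor receptor, Cd34, Flt3, Runx1, Tal1, Lmo2, Erg and Meis1. The exception was Gata2, which had 4 distal regions. All 12 early erythroid genes had a promoter region, among them Klf1, Epor, the erythropoietin receptor, Tfrc, the transferrin receptor, and Gata1, and so did all 12 housekeeping genes. Of 12 mature neutrophil genes only Mmp8 had one (8.33%), while S100a8, S100a9, Ltf, Camp and Lcn2 had none. Of 15 genes of other tissues only Apob did (6.67%), with none at Alb, Neurod1, Myod1, Ins2 or Pou5f1.

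These 5 lists passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 14 lists: adjusted p = 0.0123 for stem and progenitor regulators, 0.0137 for early erythroid genes, 0.0137 for housekeeping genes, 0.00179 for mature neutrophil genes and 0.000265 for genes of other tissues. The other 9 lists did not pass. Genes were not matched on their number of starts in this test, so a gene with many starts had more chances to have a promoter region. Granulocyte-monocyte progenitor genes had a promoter region in 12 of 16, with regions at Spi1, Cebpa, Irf8 and Mpo and none at Elane, Prtn3, Ly86 and Ms4a3 (exact adjusted p = 0.458). In the replicates' own lists 7 and 6 of the 16 had one, and Mpo had none in either. Late erythroid genes had one in 9 of 12 matched members, among them Ank1, Epb42 and Rhag but neither Alas2 nor Slc4a1. Hba-a1 and Hbb-bt belong to families of near-identical copies, so their values are uncertain. Megakaryocyte genes had one in 10 of 13, including Itga2b and Pf4. Macrophage genes had one in 7 of 13, basophil, eosinophil and mast cell genes in 5 of 10, stromal and endothelial genes in 5 of 10, NK cell genes in 4 of 9, and B cell and T cell genes in 4 of 12 each. The B cell genes with one were Pax5, Cd79b, Ebf1 and Rag1, the last in neither replicate's own list, and the T cell genes included Cd3d, Bcl11b and Cd28. In the own lists of replicates 1 and 2 the counts were 6 and 3 for macrophage and 3 and 2 for basophil, eosinophil and mast cell genes. They were 4 and 5 for stromal and endothelial, 3 and 3 for NK cell, 2 and 3 for B cell and 4 and 1 for T cell genes.

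Open promoters of progenitor genes were mostly weak. Within the 13293 genes with a promoter region, the promoter signal of Runx1 stood at percentile 2.55, that of Tal1 at 8.61 and that of Kit at 34.3, and the highest of the list was that of Flt3 at 55.5. With the upper 50% of regions by signal, the difference from other genes was −27.0 percentage points for stem and progenitor regulators, which no longer passed (exact adjusted p = 0.103), and −1.98 points for early erythroid genes, and neither mature neutrophil genes (exact adjusted p = 0.0774) nor housekeeping genes (0.541) passed. Granulocyte-monocyte progenitor genes then passed below other genes, with a difference of −37.4 points (exact adjusted p = 0.0216). Leaving out a replicate meant using the other's own list, which is also shorter, so library and list length cannot be separated here. Without replicate 1, early erythroid genes did not pass (exact adjusted p = 0.233) and T cell genes passed below other genes (0.00874). Without replicate 2, B cell genes passed below other genes (exact adjusted p = 0.0167). The share of granulocyte-monocyte progenitor genes lay above that of other genes by 14.2 points, but below it without replicate 1 (−14.5) and without replicate 2 (−12.5). Mature neutrophil genes differed from other genes by −52.5 points, but by −10.0 with the replicated-peaks list (exact adjusted p = 0.683) and in the other direction, by 17.9, with the archived list (exact adjusted p = 0.319). With a promoter window of 2500 bp, genes of other tissues did not pass (exact adjusted p = 0.134) and granulocyte-monocyte progenitor genes passed above other genes (0.0443), and with the archived list 0 of 14 lists passed Fisher's exact test.

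**Figure D2:**
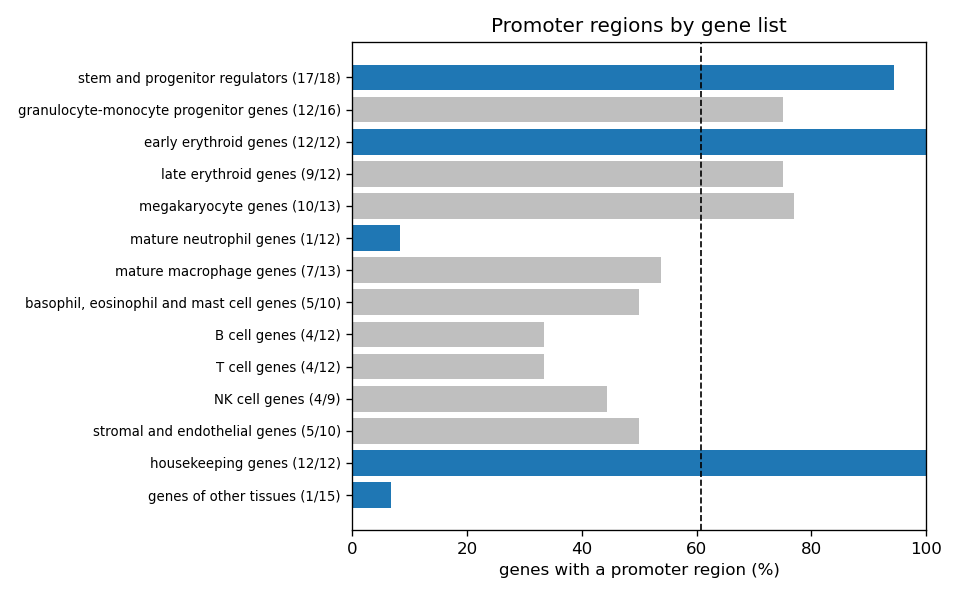
The percentage of each fixed gene list with a region within 1 kb of a transcription start (horizontal axis), with the counts beside each list's name. Blue bars passed an adjusted p of 0.05 by Fisher's exact test, grey bars did not, and the dashed line is the median share among all other protein-coding genes, near 60.8%.

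Distal regions gathered around progenitor regulators. Stem and progenitor regulators had a mean of 9.22 distal regions within 100 kb, against 3.32 in random lists matched on the length of the genes' nearest-start territory (95% of lists 1.72 to 5.33). Runx1 and Fli1 had 22 each, Etv6 20, Erg 17 and Cd34 13, while Hoxa9 had 0 and Cd27 had 1. Granulocyte-monocyte progenitor genes had a mean of 4.88 against 2.16 (1.00 to 3.63), with 10 at Ly86, 9 at Irf8, 9 at Gfi1 and 7 at Csf1r. At an unadjusted 0.05, 3 lists passed. By a two-sided permutation test with 10000 random lists, adjusted over 14 lists, stem and progenitor regulators had p = 0.0028, the smallest the permutations can give here being 0.0002 before adjustment, and granulocyte-monocyte progenitor genes p = 0.0098.

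The other 12 lists did not pass. Early erythroid genes had a mean of 3 distal regions against 1.68 in random lists (permutation adjusted p = 0.169), and mature macrophage genes 3.77 against 2.15 (permutation adjusted p = 0.161). The means were 2.67 for late erythroid, 2.77 for megakaryocyte, 1.58 for mature neutrophil and 2.1 for basophil, eosinophil and mast cell genes. They were 2 for B cell, 1.92 for T cell, 2.56 for NK cell, 4.3 for stromal and endothelial, 2.17 for housekeeping and 1.87 for other tissues' genes. The difference of stem and progenitor regulators from random lists, 5.91 regions per gene, was 2.97 without replicate 1 and 3.44 without replicate 2, and the call held in both. It was 0.984 with the upper 50% of regions by signal, 9.61 with the replicated-peaks list and 18.1 with the archived list. The difference of granulocyte-monocyte progenitor genes was 2.72 regions per gene, 1.36 without replicate 1, 1.45 without replicate 2 and 6.03 with the archived list. Their call ended with either replicate's own list (permutation adjusted p = 0.0504 without replicate 1 and 0.0882 without replicate 2) and with the archived list (0.0747). With the upper 50% of regions by signal both calls ended (permutation adjusted p = 0.172 for stem and progenitor regulators and 0.265 for granulocyte-monocyte progenitor genes), and mature macrophage genes passed (0.0308).

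**Figure D3:**
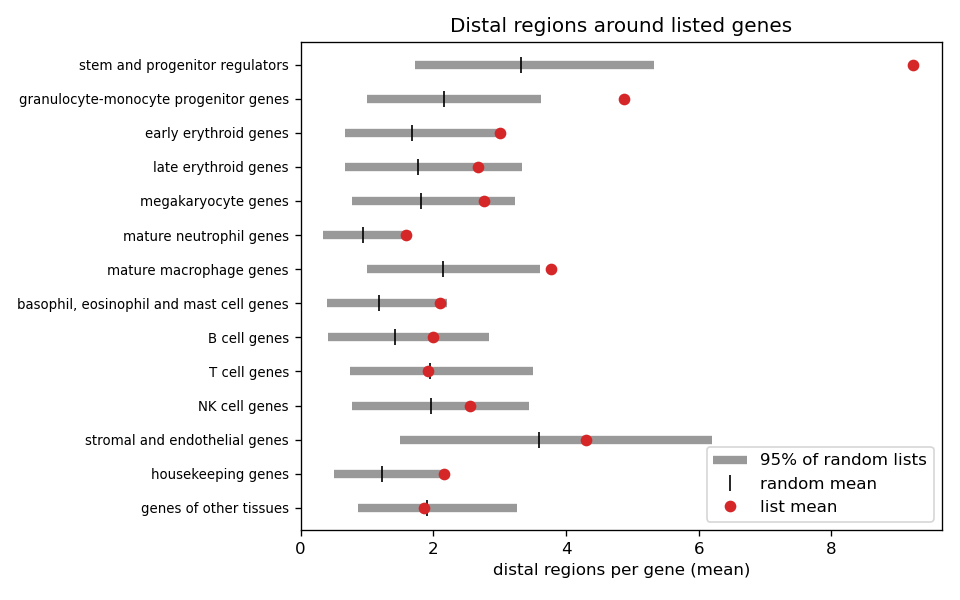
The mean number of distal regions per gene within 100 kb (horizontal axis) for each fixed list. Red points are the lists, black ticks the mean of 10000 matched random lists and grey bars the span of 95% of them, and stem and progenitor regulators stand at 9.22 against 3.32.

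Some listed promoters had a region in 1 replicate's own IDR-thresholded list alone, mostly in that of replicate 1. Over the 14 lists, 17 genes had a promoter region in replicate 1's own list only and 3 in that of replicate 2 only. Over all protein-coding genes the counts were 1128 and 184, with 11169 open in both. Of the 17, 3 each were early erythroid (Gata1, Klf1, Ermap), late erythroid (Hba-a1, Epb42, Rhag), macrophage (Cd68, C1qc, Ccr2) and T cell genes (Bcl11b and Cd28 among them). No list passed the exact McNemar test, adjusted or not: the smallest unadjusted exact p was 0.25, which is the smallest that 3 discordant genes can give. With the less strict pseudoreplicated lists, 10 listed genes were open in replicate 1 alone and 4 in replicate 2 alone. There 0 early erythroid, late erythroid or T cell genes differed between the replicates, and all 12 early erythroid genes were open in both. Macrophage genes had 1 in each direction. With the same number of strongest regions from each replicate, 9 stem and progenitor regulators were open in replicate 2 alone and 0 in replicate 1 alone (exact p = 0.00391, exact adjusted p = 0.0547). That setting left replicate 2's list whole and dropped the weak regions of replicate 1.

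Binding sequences of CTCF, PU.1 and RUNX factors marked distal summits. A CTCF consensus lay within 50 bp of 7.94% of 52605 distal summits against 0.0367% of flanking windows, log2 odds 7.86 (95% interval 7.37 to 8.34). The sequence of PU.1, a myeloid transcription factor, was found at 6.94% against 0.478% (3.95, 3.81 to 4.10), and that of RUNX at 6.44% against 1.13% (2.59, 2.49 to 2.69). An NRF1 match lay at 0.173% against 0.0302%. NF-E2 (3.34), YY1 (2.42), ETS (2.27), E2F (2.24) and an E-box with GATA (2.11) were also among the 10 highest, by log2 odds. REST, a repressor of neuronal genes, matched 85 summits and 0 of 92674 flanking windows, which made its share at summits at least 49.9 times the share that 3 flank matches allow. GATA alone (0.66) and C/EBP (0.56) had smaller odds. A GATA match lay at 8.91% of summits, a larger share than that of CTCF, but also at 5.82% of flanks. C/EBP matched 5.71% against 3.93%. With summits and flanks both drawn to match on GC content, the log2 odds of GATA and C/EBP rose to 1.38 and 0.98, while NRF1 fell to 1.32, below GATA. By Fisher's exact test, two-sided, 21 of 33 motifs were more frequent at summits and 10 less frequent at adjusted p under 0.05.

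Promoter summits shared CTCF, REST, NRF1, ETS, YY1, PU.1 and NF-E2 sequences with distal summits, and NFY, SP and KLF, whose factors bind many promoters, joined the 10 motifs with the highest odds. With the upper 50% of regions by signal, NF-E2 no longer passed at promoters (log2 odds 1.95, Fisher's exact test, adjusted p = 0.0703). NRF1 (log2 odds 5.65), CTCF (5.27), ETS (5.01), YY1 (3.97), NFY (3.91), SP (2.95), PU.1 (2.73), KLF (2.26) and NF-E2 (2.10) were more frequent at 14789 promoter summits than in 17560 flanks, and REST matched 25 summits and 0 flanks. A KLF match lay at 22.5% of promoter summits against 5.70% of flanks. In all, 16 motifs were more frequent and 11 less frequent by Fisher's exact test at adjusted p under 0.05. GATA was less frequent at promoter summits (−0.80), as was C/EBP (−0.28). With summits and flanks both drawn to match on GC content, both turned, to 0.83 and 0.76. That matching left out GC-rich summits for which flanks were too few, so its values cover only the summits kept and not all 14789. The same matching lowered the log2 odds of SP to 1.42, of KLF to 0.97 and of NRF1 to 3.83, and 18 motifs then passed, of which 14 were among the 16. Promoter summits had a median GC content of 63.4% against 48.5% in flanks, and distal summits 51.5% against 45.5%.

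**Figure D4:**
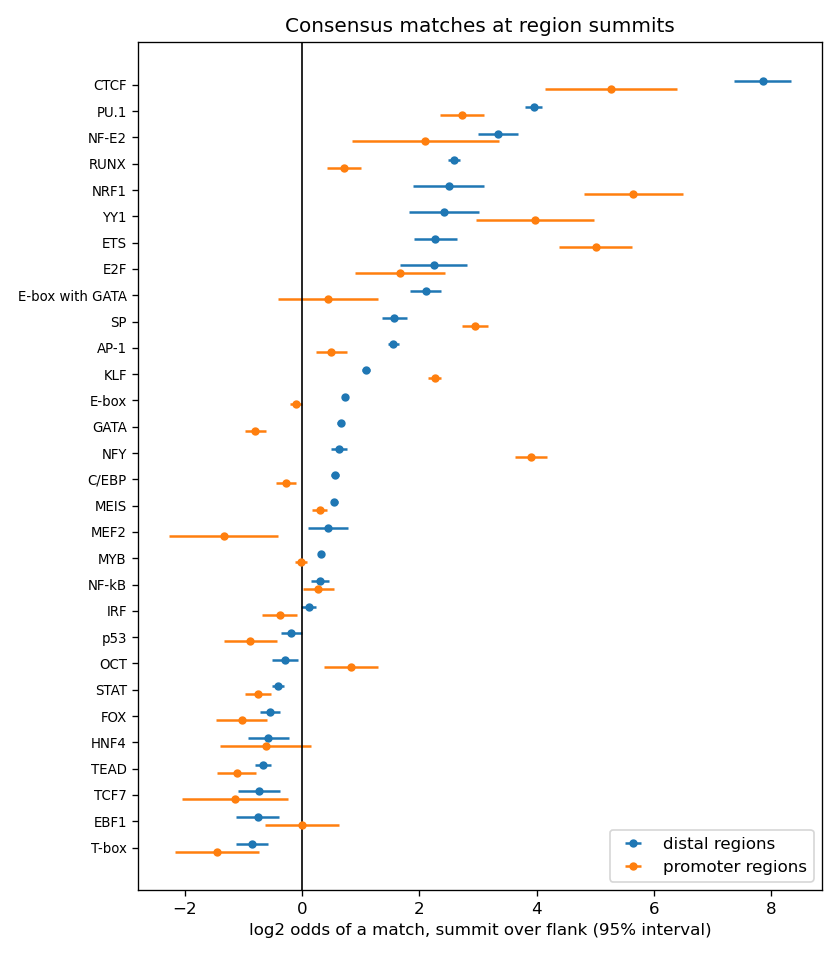
The log2 odds of a consensus match within 50 bp of the summit over flanking windows (horizontal axis), with 95% intervals, for 30 motifs that had at least 10 summit matches and any flank match in both classes. Blue points are distal and orange points promoter regions, and CTCF stands at 7.86 and 5.27.

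Accessible regions lay near the positions of textbook enhancers, which drive blood regulators in blood progenitors. All 22 listed elements, placed by their offset from a transcription start, had a region within 2 kb. Any region near the offset from any annotated start counted, so a hit does not show that the named element itself was open. Random genes with an open promoter gave a mean of 8.31 regions at the same offsets. None of 1000 draws gave 22 (one-sided permutation p = 0.000999, the smallest these draws can give). The Gata2 element at −77 kb met a region on chromosome 6 at 88116355 to 88117584 (mm10, intergenic, 1230 bp), and that at 9.5 kb an intronic region at 88202946 to 88203628. The Runx1 element at 23 kb met an intronic region on chromosome 16 at 92800766 to 92802254, and the Cebpa element at 37 kb an intergenic region on chromosome 7 at 35156303 to 35157110. The Irf8 element at 56 kb met a region on chromosome 8 at 120792577 to 120793189 (intron).

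Each replicate's own list held 20 of the 22 regions met, and those at Fli1 12 kb and Gfi1b 16 kb were in neither. The strongest region met was a promoter region for 4 elements (Spi1 −14 kb, Tal1 −4 kb, Lyl1 0 kb, Hhex 1 kb), and Lyl1 0 kb and Hhex 1 kb met a region at every random gene by construction. The region for Spi1 −14 kb ended at 91070884 on chromosome 2, before the Spi1 gene begins at 91082390, so it was a promoter region of another gene. At random positions 3 to 100 kb from the same genes, a control chosen after seeing the data, the mean was 7.32 and the highest of 1000 draws 15 (one-sided permutation p = 0.000999). That control had fewer tries: listed elements were sought from every annotated start of the gene, up to 7, and random positions from 1 start each. It also put positions at least 3 kb away in place of Lyl1 0 kb and Hhex 1 kb. The comparison with 22 is therefore not like for like.

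Pde4d, a cAMP phosphodiesterase gene, had the most distal regions of any protein-coding gene, 57. Gse1 had 31, Foxp1 and Elmo1 29 each, Nav2 28, Frmd4a and Tiam1 27 each, and Bach2, Ubash3b and Ppm1h 26 each. Unlike in the list test, these counts were not matched on territory length, so long genes with many starts can rank high for that alone. The strongest promoter regions were at Gm5141 and 6720489N17Rik (signal 26.2 each), Platr25 (25.8), Gm20594 (25.6), Smn1 (25.3), Zfp97 (24.4), Tph2 (24.3), Snap25 (24.2), which had a REST match, Glra1 (24.0) and Gm49359 (23.6), against a median of 10.5 over genes with a promoter region. The Gm20594 region matched the mitochondrial genome, and those of Platr25 and Zfp97 had a near-identical copy elsewhere.

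The strongest distal region lay between genes on chromosome 2 at 69355472 to 69355731 (mm10, 260 bp, signal 45.6), 12985 bp from a start of Abcb11, and held a 129 bp stretch identical to the mitochondrial genome. The second, on chromosome 6 at 9889880 to 9890223 (signal 35.2), and that on chromosome 5 at 60042657 to 60043142 (31.1) also matched mitochondrial sequence. The third lay in an intron on chromosome 16 at 18533130 to 18533394 (34.5). Regions on chromosome 8 at 20424434 to 20425000 (32.1), 20122102 to 20122643 (30.6) and 20550058 to 20550585 (28.6) were near-identical copies, so their values are uncertain. The others of the 10 lay between genes on X at 143482940 to 143483174 (32.5) and on chromosome 4 at 88757558 to 88757853 (30.0) and 127015625 to 127016110 (28.4).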

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

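The test of the weaker peak list of replicate 2, the tests of genes on X, and the slope and tolerance measures on X were chosen only after the results they concern were seen. All 3 patterns were themselves picked after the main values were seen.

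Some peaks past the IDR threshold were absent from the conservative list, the main set; whether other lists hold them was not examined. The ranked list behind the conservative set held 101 such peaks on 15 unplaced scaffolds, with a median signal of 4.97. It also held 161 on chromosomes that the conservative list leaves out. These merged to 86 regions covering 51.1 kb, with a median signal of 6.40, and chromosome 9 held the most, 16. No explanation was tested for either set.

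The 200 strongest regions, with a signal of at least 20.4, included sequence that occurs elsewhere in the genome. Of them 3.5% (7) matched the mitochondrial genome, whose many copies per cell are also cut by the transposase, against 0 of 200 regions of like width (Fisher's exact test, two-sided, p = 0.0148). A near-identical copy elsewhere was found for 9.5% (19), against 5 of the 200 of like width (exact p = 0.00514). CTCF or REST sequences lay at 5% of their summits (exact 95% interval 2.42 to 9.003), against 6.67% of all regions. Each share met the bound set beforehand for excluding that explanation for the set as a whole, under 5% for mitochondrial sequence and under 10% for copies. The latter was met by 1 region only. The search for copies covered chromosomes 1 to 19, X and Y but no scaffolds, so 9.5% is a minimum and that bound decides little. Both shares lay far below the 20% and 50% that the explanations would need. CTCF or REST sites that depart from the consensus were not counted, so they are not excluded. In all, 165 of the 200 had none of these features. For the 10 strongest distal regions mitochondrial sequence (3 regions) and copies (3 regions) remain open, since reads from those sequences could add to their signal. The strongest promoter regions of Gm20594, Platr25 and Zfp97 are in the same position. No biological explanation was tested, since the design has 1 group.

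Regions of replicate 1 that were not found in replicate 2 numbered 13179. Of these, 92.2% (12148) had a region in replicate 2's less strict pseudoreplicated list, so the list threshold of replicate 2 may account for most of them. A larger share of granulocytes or monocytes in replicate 1 would raise PU.1 sequences in regions of replicate 1 alone, but these were rarer there than in regions of replicate 2 alone. The log2 odds within 10 classes of signal were −0.74 (95% interval −0.96 to −0.51), from 5.38% of 11318 distal regions against 8.78% of 2757. That interval lay below the bound of 0.50 set beforehand. The classes were ranked within each replicate's own list, however, and most regions of replicate 1 alone were also in replicate 2's less strict list. The contrast therefore cannot exclude a larger share of granulocytes or monocytes. A larger share of erythroid cells in replicate 1 also stays open. GATA sequences had log2 odds of 0.45 (0.22 to 0.67), from 9.89% against 7.51%, and that interval holds both values above and below the bound of 0.50 set beforehand. Library depth is unknown and cannot be told apart from the list threshold. The labels of replicate 1 name 2 instruments and those of replicate 2 none, so a batch difference was not testable.

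Chromosome X, of which male cells have a single copy, held 9.28 regions per Mb, against 26.7 on autosomes (21.8 to 34.9 by chromosome). Fewer genes do not account for this, since X had 1.67 regions per gene and the lowest autosome 2.08. Fewer reads on a single X could lower −log10 p at a given signal, but the median ratio of X regions to autosomal regions of like signal was 1 (bootstrap 95% interval 0.995 to 1), above the excluding bound of 0.90 set beforehand. That test cannot see a loss of reads that lowers signal and −log10 p together, and 28.7% of X regions lay within 1% of the autosomal median at like signal, against 17.9% of autosomal regions. Fewer reads could also drop weak regions below the threshold. With −log10 p divided by 2, autosomes kept 19.5 regions per Mb, past the bound of 18 that had been set beforehand for excluding this. After that value was seen the divisor was changed and the bounds were kept. Across autosomal regions −log10 p rose with signal to the power of 1.37, and 2 to that power became the divisor. That slope runs across regions of the same libraries, so it does not show how −log10 p falls with fewer reads. With the changed divisor autosomes kept 15.7 regions per Mb, between the bounds of 12 and 18. The planned test thus met its excluding bound and the changed one did not decide, so this explanation is not settled here. Both values leave more regions than X has. The median signal was higher on X, 9.46 against 8.35. A lower accessibility of X was not tested separately.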

How the results depend on the processing

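The archived list, the background without receptor families and the enhancer positions around the same genes were chosen after seeing the data. Of the values that answer a comparison, 47 recomputed values stayed and 29 moved. Those that stayed kept their side of the threshold or were counts of passing lists or motifs within a fixed ratio of the main count. A change from 5 to 6 passing lists thus was not called a move. Every recomputed overlap share, correlation and promoter share lay outside the spread of its main value and is among the 29. Of the recomputed values for single lists and motifs, 423 kept direction and side, 17 kept direction but no longer passed, 4 newly passed and 32 reversed. The cause was not tested except where stated.

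The share of replicate 1 found in replicate 2, and of replicate 2 in replicate 1, was 70.0% and 88.5% with 50% reciprocal overlap, 69.8% and 88.2% with summits within 100 bp, 80.1% and 92.6% with pseudoreplicated lists, 71.8% and 90.8% with the upper 50% of each list, and 78.8% and 79.5% with equal numbers of regions. Spearman's rho was 0.885 for −log10 p, 0.919 for promoter, 0.855 for distal regions and 0.883 for all ranked peaks. The promoter share was 22.5% in the series IDR list, 17.0% in the replicated list, 25.9% in the upper 50%, 13.3% in the archived list, 18.8% with a 500 bp window, 27.1% with 2500 bp, 29.2% for peaks not merged, and 26.8% to 30.2% with a replicate left out. A wider window takes in more regions by construction.

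With the upper 50% of regions, which removes weak regions by construction, 2 gene lists passed for promoters and 1 for distal regions. Reversed promoter differences, in percentage points from other genes, were −27.0 for stem and progenitor regulators, −37.4 for granulocyte-monocyte progenitor, −1.98 for early erythroid and −20.6 for megakaryocyte genes. Reversed distal differences, in regions per gene from random lists, were 0.434 for T cell, −0.445 for NK cell and 0.192 for other tissues' genes. With the archived list, 0 lists passed for promoters and 1 for distal regions. Promoter differences became 17.9 for neutrophil, 18.6 for macrophage, 1.24 for B cell, 1.24 for T cell, 4.02 for NK cell and 26.3 for stromal genes, the distal difference 1.38 for T cell genes, and the log2 odds of the E-box with GATA at promoters −0.13.

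With the replicated list, promoter differences were 8.58 for macrophage, 9.43 for NK cell and 21.7 for stromal genes, and the distal difference of T cell genes was 1.43. With the series IDR list, distal differences were 0.124 for T cell and 0.0982 for other tissues' genes. With a 2500 bp window the promoter difference of stromal genes was 5.23. Without territory matching, distal differences were −0.466 for neutrophil and −0.0549 for B cell genes. With GC-matched windows, which also left out summits, the promoter log2 odds were 0.83 for GATA and 0.76 for C/EBP.

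With a replicate left out, the promoter difference was −14.5 to −12.5 for granulocyte-monocyte progenitor and −13.5 to −10.1 for megakaryocyte genes, the distal difference of T cell genes 0.101 to 0.454, and 1 list passed for distal regions either way. Odds of promoter over distal recurrence, 104 values for single motifs at distal regions and the enhancer call kept direction and side under each alternative run. A region lay near 12 to 22 of the 22 listed enhancers. Depth is unknown, so its limit on weak regions could not be given.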

Other observations

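No test in this part was planned. REST sequences lay at 110 regions, whose median signal stood at percentile 64.1 of all regions (quartiles 36.0 to 80.7), and CTCF sequences at 4387, with a median at percentile 55.6. Chromosome Y held 19 regions.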
